A study of Mus musculus with 34 samples.

How the data were processed

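The authors hybridised 200 ng of total RNA of each mouse, amplified and labelled with Cy5, together with a Cy3-labelled universal mouse reference RNA on 4-by-44,000 Agilent mouse arrays. Per the file headers, scanner images were read with Agilent Feature Extraction 10.1.1.1. The instilled volume was 40 µl; time of day, order of hybridisation and order of collection were not given in the sources used here. The deposited scanner files give background, foreground intensity, processed signal and quality flags per spot, not on a log2 scale, per the file headers. Median foreground and median background signals were used; the mean foreground signals named in the plan made before the files were seen were not used here, so median signals replaced them.

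Of 43379 spots that are not controls, spots flagged as non-uniform or population outliers in the sample or reference channel were left out, which left 0.018% of values missing in the genes tested. Spots of 1 probe were averaged, giving 41174 probes. A probe entered the fit when its sample channel was well above background on at least 0.5 of the arrays of at least 1 group, and genes with more than 3 missing values were left out. Of the 25253 probes that passed, 17250 carried a gene name. Names were matched through RefSeq accessions (23374 probes, 16535 genes) from a table built on assembly GRCm38.p6, which was used for names only; no coordinates were used, and the array header gives build mm8. For each gene the probe with the highest mean log2 sample-channel signal over the 34 arrays was kept, which gave 19798 genes, 12347 with a name and 7451 known by accession only; 11981 were well above background on all arrays. Genes not well above background on any array of a group numbered between 21 and 518 per group and have only a bound there, among them several liver and neutrophil transcripts.

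Signals were background-corrected with normexp (offset 50) and loess-normalised within arrays in limma 3.58.1 (R 4.3.3, data.table version 1.17.8; plots with python 3.11.15 and matplotlib 3.10.9). Log2 ratios of sample Cy5 over reference Cy3 were fitted with lmFit and eBayes with a mean for each of the 6 groups and 28 residual degrees of freedom. The all-days effect is the mean of the 3 day effects, each with the same weight. Benjamini-Hochberg adjustment ran over the genes of a comparison, with a threshold of 0.05. Of the genes past the threshold, the 12 of largest change in each direction were named; where fewer than 6 passed, the 6 genes of smallest unadjusted p were named as values that did not pass, and in described lists up to 4 members of smallest unadjusted p. Genes known by clone name or accession were tested but not named. The 38 lists (22 pathways and 16 cell types) were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, then with an estimated correlation and with fry. Marker scores are means over the markers of a list of the deviation from the median of all arrays.

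The values deposited by the authors have column medians from -0.055 to -0.033 and correlates at 0.995 to 0.998 (slope 0.99 to 0.996) with loess-normalised log2 ratios of the median signals without background correction. Scale, centring and direction of those values were found from its values in this way, as their own description of them was not used here; none of the 3 stays unknown.

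The methods were tested on simulated data, in which the residuals of the real arrays were shuffled over the arrays. Genes were then shifted by a fixed size, 150 genes per size over 3 runs. The shuffle breaks the tie of exposure with slide and array position, so the rates below hold only without that tie. At log2 changes of 0.5, 1, 1.5 and 2, the percent recovered was 34.7, 93.3, 96.7 and 96.7 for day 1, 30.7, 78, 91.3 and 98 for day 3, 36.7, 79.3, 92 and 98 for day 28, 76.7, 96, 98.7 and 100 for all days together, and 13.3, 67.3, 85.3 and 94.7 for the difference between days. For the controls it was 32, 80, 94 and 97.3 for day 1 to day 3, 41.3, 87.3, 94 and 94 for day 1 to day 28, and 29.3, 77.3, 90 and 97.3 for day 3 to day 28. False calls were 0%, 0.2%, 3.4%, 0%, 2.2%, 0.2%, 38.9% and 4.3% of calls in that order of comparisons; the 38.9% is 302 of 777 calls for controls day 1 to day 28. For lists, only the matrix list was moved, by 0.5 on all exposed arrays, and tested over all days together. It was called in 10 of 10 runs with each correlation. Among the other of the 38 lists, over the 10 runs, 97 calls came with the preset and 0 with the estimated correlation. Smaller shifts, other lists and single days were not tried, so the power of the list tests there is not known.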

Results

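Heart RNA of female C57BL/6 mice was hybridised to 34 two-colour mouse gene expression arrays, 1 animal per array. The mice had received 162 µg of Printex 90, a carbon black nanoparticle, or the vehicle alone by intratracheal instillation, and hearts were taken 1, 3 or 28 days later. The labels give each array its own sample number, and the series design speaks of RNA from individual mice. The 6 groups held 6 control and 6 carbon black arrays at day 1, 6 and 5 at day 3, and 6 and 5 at day 28. The tissue was a random section containing both ventricles. The sample RNA carried Cy5 and a pooled reference RNA from many mouse tissues carried Cy3 on all arrays. A value above 0 on the log2 ratio scale thus means more transcript in the heart sample than in the reference. Between 42.8% and 66.6% of spots were well above background in the sample channel (median 54.9%). The median sample-channel signal lay between 99 and 155, and no sample-channel spot was saturated. Of 41174 probes, 25253 passed the filter on dim probes and represented 19798 genes.

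Before the exposed and control groups were compared, the arrays were scored for markers of tissues that a random section of heart can contain. Atrial transcripts, which encode the atrial myosin light chains Myl7 and Myl4, sarcolipin and atrial natriuretic peptide, were low on 5 arrays. Their scores, as mean deviations of the log2 ratio, ran from -3.13 to -1.94 against -0.73 or above on the other arrays. These 5 arrays were control day 1 replicate 2, carbon black day 1 replicate 6, control day 3 replicate 4, carbon black day 3 replicate 2 and control day 28 replicate 2. Both arms thus held such arrays. Of the 50 genes with the largest loadings on the first principal component, which took 25.9% of the variance, 10 were adipose markers, with the lipid droplet proteins Cidec and Plin1 at the top, and 7 were atrial markers. Group membership explained 4.1% of that component and slide 15.5%. Slide explained 57.4% of component 2 (18.4% of the variance) and group 18.5%, and group explained 34.6% of component 3 (9.4% of the variance) and slide 24.9%. Such shares rise by chance with the number of levels, here 14 slides against 6 groups over 34 arrays. The shares of slide and group therefore cannot be compared directly. As a random block, slide had a consensus correlation of 0.054 over genes. Liver transcripts, such as those for albumin and apolipoproteins, scored highest in control day 3 replicates 5, 6 and 4 (3.68, 2.71 and 1.94). The group means ran from -0.30 ± 0.39 (SD, n = 6) in control day 28 to 1.30 ± 1.71 (SD, n = 6) in control day 3. Airway secretory transcripts such as Scgb1a1 and Scgb3a1 scored highest in control day 3 replicate 1 (3.01), against a mean of 0.05 ± 0.08 (SD, n = 6) in control day 1. The median correlation of an array with the other arrays of its group was between 0.839 and 0.958 for 33 arrays and was 0.768 for carbon black day 1 replicate 6.

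**Figure D1:**
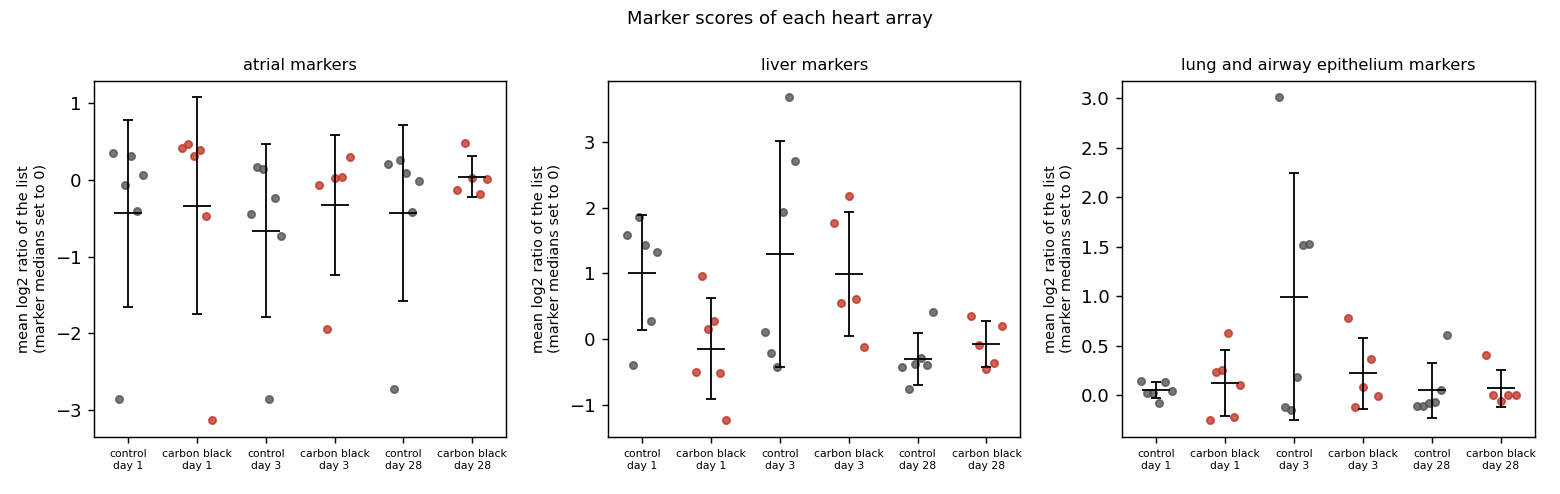
Marker scores of each array (points) for atrial, liver and lung or airway lists, on the log2 ratio scale as deviations from the median of all arrays, with group mean and SD. Groups are control and carbon black at day 1, 3 and 28. Atrial scores of 5 points lie between -3.13 and -1.94, and the highest liver and airway scores, 3.68 and 3.01, are both in control day 3.

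The broadest question of the design is which heart transcripts differ between exposed and vehicle-treated mice when the effect is averaged over the 3 days. Ephx2, the soluble epoxide hydrolase that breaks down epoxyeicosatrienoic acids, had the largest rise among the genes that passed. Its mean log2 ratio was 5.36 (SD 0.82, n = 18) in controls and 6.30 (SD 0.66, n = 16) in exposed hearts, a log2 fold change of 0.95 ± 0.26 (SE; limma, Benjamini-Hochberg adjusted p = 0.0471). Ldhb, the heart form of lactate dehydrogenase, rose by 0.89 ± 0.23 (adjusted p = 0.0448), the membrane-bound carbonic anhydrase Car14 by 0.88 ± 0.19 (adjusted p = 0.0339). Cardiac troponin I (Tnni3) rose by 0.82 ± 0.22 (adjusted p = 0.0461). Among the genes that fell, osteopontin (Spp1) changed by -0.66 ± 0.17 (adjusted p = 0.0448) and gamma-actin (Actg1) by -0.48 ± 0.13 (adjusted p = 0.0471). The mean log2 ratio of Spp1 was -7.52 in controls and -8.18 in exposed hearts, so its heart signal lay far below the reference. Basement membrane collagen (Col4a1) changed by -0.41 ± 0.10 (adjusted p = 0.0378) and the integrated stress response factor Atf4 by -0.38 ± 0.10 (adjusted p = 0.0448). In all, 386 of 19798 genes passed the threshold in the limma fit, 262 higher and 124 lower. That balance depended on scaling, with 1336 higher and 0 lower under median centring and 819 higher and 672 lower in the values deposited by the authors. At the same time 3621 genes had an unadjusted p under 0.05 against 990 expected by chance.

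Further genes that rose carry diverse functions. They included the mitochondrial ribosomal protein Mrpl55 (0.74 ± 0.20) and the NF-kappa-B inhibitor Nfkbia (0.74 ± 0.20). To these came the splicing factor Hnrnpa1 (0.68 ± 0.16), the glutathione transferase Gstm1 (0.68 ± 0.15), the proton pump subunit Atp6v1d (0.68 ± 0.18) and the adenosine-forming ectonucleotidase Nt5e (0.67 ± 0.14). Their limma adjusted p ran from 0.0317 to 0.0492. The other named genes that fell were Emp1 (-0.41 ± 0.11), the collagen-binding glycoprotein Sparc (-0.38 ± 0.08), Niban2 (-0.36 ± 0.08) and Mfap3 (-0.35 ± 0.07). Lower too were polyubiquitin Ubb (-0.35 ± 0.08), Sfn (-0.35 ± 0.09), Gde1 (-0.35 ± 0.09) and the vesicle transport GTPase Arf1 (-0.33 ± 0.07), also with limma adjusted p from 0.0317 to 0.0485. Under median centring in place of loess the changes of Sparc (0.02), Ubb (0.11), Sfn (0.01) and Arf1 (0.04) turned to the other side of 0. That scaling moved the median of all genes by 0.188, and these 4 genes stayed below it. Between 13 and 16 of the 16 exposed arrays lay on the side of the change for each of the 24 genes of largest change (12 higher and 12 lower), counted against the mean of the controls of the same day on the arrays that selected the genes. Over the 386 genes the median absolute log2 fold change was 0.36 over the days together, and 0.36, 0.42 and 0.30 at day 1, day 3 and day 28. Only 36 of them, 35 higher and 1 lower, changed by 1.5-fold or more. Of these 24 genes, 11 had other probes on the array, all of the same sign for 9 of them. The other probe of Mfap3 gave 0.01, and the other probes of Hnrnpa1 gave 0.08 and 0.16.

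The 386 calls depended on how the arrays were blocked and on the signals and arrays used. With slide as a fixed block no gene passed in limma (2850 at unadjusted p under 0.05, lowest adjusted p 0.0939). The median change of the 386 genes in their direction was then 0.364, against 0.361 without the block. That block left 15 residual degrees of freedom against 28. With slide as a random block 437 genes passed, 381 of them among the 386. With scan day as a fixed block no gene passed (3209 at unadjusted p under 0.05, lowest adjusted p 0.0591) and the median was 0.353. These medians come from the arrays that selected the genes. All 10 arrays at position 4 of a slide were carbon black arrays and 12 of 18 control arrays were at position 1. With position as a fixed block, an alternative chosen after seeing the data, no gene passed (1501 at unadjusted p under 0.05, lowest adjusted p 0.564) and the median change was 0.27. No gene passed with Agilent processed signals. Without the 3 control day 3 arrays of high liver score, also left out after seeing the data, 1 gene passed. Leaving out 1 array at a time gave between 0 and 947 genes. The count was 0 without carbon black day 3 replicate 3, carbon black day 3 replicate 5, carbon black day 28 replicate 3 or control day 28 replicate 4, and 947 without control day 3 replicate 3.

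**Figure D2:**
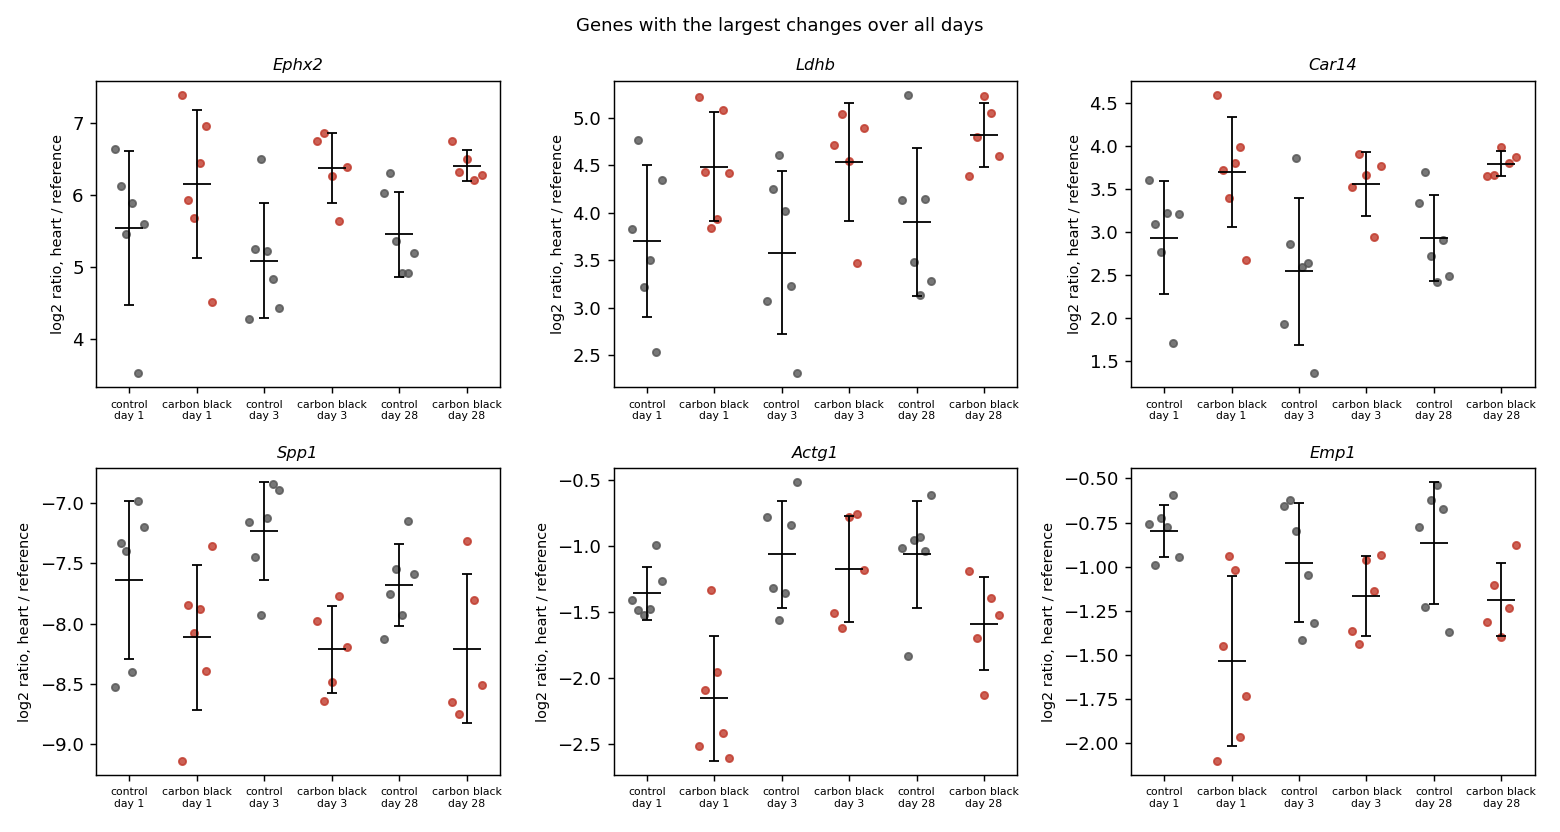
Log2 ratio of sample over reference for 6 of the named genes on each array (points) with group mean and SD, for control and carbon black groups at day 1, 3 and 28. Ephx2, Ldhb and Car14 rose by 0.95, 0.89 and 0.88 over the days together, and Spp1, Actg1 and Emp1 changed by -0.66, -0.48 and -0.41. The arrays of both arms overlap in each panel.

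Of the 38 gene lists fixed before the data were examined, 5 shifted over the days together in camera with its preset correlation. Glucocorticoid-responsive genes had a median log2 fold change of 0.25, with 20 of 21 members above 0 (adjusted p = 0.00166, and adjusted p = 0.979 with an estimated correlation). The FK506-binding co-chaperone Fkbp5 changed by 1.07 ± 0.30, the glucocorticoid-induced leucine zipper Tsc22d3 by 0.35 ± 0.10, Per1 by 0.64 ± 0.24 and Hif3a by -0.29 ± 0.10. None of these members passed over all genes, and 2 higher and 1 lower did when adjusted over the list alone. Fatty acid oxidation genes had a median of 0.21, with 27 of 31 members above 0 (adjusted p = 0.00199, and adjusted p = 0.979 with an estimated correlation). In this list 1 member passed over all genes and 1 adjusted over the list alone. Acot1 changed by 0.66 ± 0.25 and Cpt1b, which carries fatty acids into mitochondria, by 0.30 ± 0.13. Contractile genes had a median of 0.19, with 18 of 20 members above 0 (adjusted p = 0.00457, and adjusted p = 0.979 with an estimated correlation). Tnni3 passed over all genes and 4 members passed adjusted over the list alone, with Myl3 at 0.67 ± 0.20, Myh6 at 0.54 ± 0.19 and Actc1 at 0.43 ± 0.14. Matrix genes had a median of -0.17, or 0.17 with median centring against 0.188 for all genes there. In the main fit 28 of 36 members were below 0 (adjusted p = 0.00132, and adjusted p = 0.979 with an estimated correlation). Sparc, Col4a1 and Spp1 passed over all genes, 5 members passed adjusted over the list alone, and Col8a1 changed by -0.48 ± 0.14. Cell cycle genes had a median of -0.13, or 0.19 with median centring, with 22 of 24 members below 0 (adjusted p = 0.00199, and adjusted p = 0.979 with an estimated correlation). None passed over all genes and 2 did adjusted over the list alone, with the mitotic kinases Aurka at -0.30 ± 0.09 and Plk1 at -0.28 ± 0.09.

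None of the 5 lists kept its call, each with an adjusted p = 0.979 with an estimated correlation, and 93 of 100 splits of the arrays within days gave as many called lists. The medians with slide as a fixed block were 0.32 for glucocorticoid-responsive, 0.21 for fatty acid oxidation, 0.11 for contractile, -0.18 for matrix and -0.11 for cell cycle genes. With scan day as a block they were 0.24, 0.22, 0.16, -0.17 and -0.08. Within the 10 slide pairs, the glucocorticoid-responsive median was above 0 in 8 pairs (-0.06 to 1.03), the fatty acid oxidation median in 6 (-0.59 to 0.87) and the contractile median in 7 (-0.30 to 0.68). The matrix median was below 0 in 7 pairs (-0.85 to 0.54) and the cell cycle median in 7 (-0.27 to 0.10). Outside these lists, Gsr, which regenerates reduced glutathione, rose by 0.35 ± 0.07 and the sulfiredoxin Srxn1 fell, with a change of -0.29 ± 0.08 (limma adjusted p = 0.0317 and 0.0448). The Nrf2 target list that holds both had a median of 0.00 over 30 members.

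At day 1 after instillation no single gene passed the test, and 12 lists were called with the preset correlation, with the lowest medians in fibroblast (-0.84) and liver markers (-0.74). The 6 genes of smallest unadjusted p that carry a name were all lower. These were Fbn1, the microfibril protein fibrillin-1, by -0.86 ± 0.20 (SE; 6 against 6 arrays), the vascular and progenitor surface protein Cd34 by -0.73 ± 0.16, Col4a1 by -0.71 ± 0.16, Cacybp by -0.50 ± 0.11, Arf1 by -0.50 ± 0.12 and the adaptor Nck1 by -0.40 ± 0.09. Each had a limma adjusted p = 0.373 and 6 of 6 exposed arrays below the control mean, counted on the arrays that selected the genes. Fibroblast markers had a median of -0.84 with 15 of 16 members below 0 (camera, adjusted p = 8.91e-06, and adjusted p = 0.554 with an estimated correlation), among them Lum at -1.23 ± 0.41, Dpt at -1 ± 0.29, Col3a1 at -1 ± 0.38 and Col1a1 at -0.87 ± 0.32. None passed over all genes and 2 did adjusted over the list alone. Matrix genes had a median of -0.35, or 0.10 with median centring, where the median of all genes was 0.208. In the main fit 26 of 36 members were below 0 (adjusted p = 8.48e-08, and adjusted p = 0.554 with an estimated correlation), with Sparc at -0.55 ± 0.14 and Col6a1 at -0.45 ± 0.15. Adjusted over the list alone 10 members passed, and none over all genes. Macrophage markers had a median of -0.47 with 19 of 21 members below 0 (adjusted p = 6.37e-06, and adjusted p = 0.554 with an estimated correlation). They included the fractalkine receptor Cx3cr1 (-0.49 ± 0.16), Ms4a7 (-0.47 ± 0.16), Adgre1 (-0.66 ± 0.24) and the complement subunit C1qc (-0.62 ± 0.25), none of which passed over all genes or adjusted over the list alone.

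Further lists were called at day 1 in the same test. Glucocorticoid-responsive genes had a median of 0.35 with 17 of 21 members above 0 (adjusted p = 4.81e-05, and adjusted p = 0.554 with an estimated correlation), led by Fkbp5 (1.61 ± 0.50), the mTOR inhibitor Ddit4 (1.40 ± 0.48) and the adrenaline-forming enzyme Pnmt (0.84 ± 0.30). In limma 0 members passed over all genes or adjusted over the list alone against 7 at unadjusted p under 0.05. Fatty acid oxidation genes had a median of 0.17 (27 of 31 above 0, adjusted p = 0.00629, and adjusted p = 0.775 with an estimated correlation), with Acot1 at 0.89 ± 0.42. T and B cell markers had a median of 0.28 (14 of 15 above 0, adjusted p = 0.0275, and adjusted p = 0.818 with an estimated correlation), with the B cell antigen Ms4a1 at 1.51 ± 0.89. Interferon-responsive genes had a median of -0.20, or 0.11 with median centring (19 of 27 below 0, adjusted p = 0.000731, and adjusted p = 0.554 with an estimated correlation). Bst2 stood at -0.67 ± 0.19, and 2 members passed adjusted over the list alone. Ribosomal protein genes had a median of -0.22, or 0.39 with median centring (24 of 29 below 0, adjusted p = 8.91e-06, and adjusted p = 0.641 with an estimated correlation). Heat shock genes had one of -0.13, or 0.36 with median centring (15 of 20 below 0, adjusted p = 0.0331, and adjusted p = 0.554 with an estimated correlation). Rps2 stood at -0.42 ± 0.11 and the chaperone Hsph1 at -0.74 ± 0.20, and 1 member of each list passed adjusted over the list alone. Smooth muscle and pericyte markers had a median of -0.37 (13 of 14 below 0, adjusted p = 0.035, and adjusted p = 0.641 with an estimated correlation), with alpha-actin (Acta2) at -0.60 ± 0.38. Endothelial markers had a median of -0.26 (14 of 18 below 0, adjusted p = 0.0123, and adjusted p = 0.775 with an estimated correlation), with the angiopoietin receptor Tek at -0.80 ± 0.33, but it was 0.03 with median centring, 0.22 without background correction, 0.26 with Agilent's processed signals, 0.20 in the authors' value table and 0.06 without carbon black day 1 replicate 6. Liver markers had a median of -0.74 (8 of 9 below 0, adjusted p = 0.000258, and adjusted p = 0.554 with an estimated correlation; 3 passed adjusted over the list alone). The liver score was 1.01 ± 0.87 (SD, n = 6) in controls and -0.14 ± 0.77 (SD, n = 6) in exposed hearts.

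At day 1, limma called 0 genes (1428 at unadjusted p under 0.05, 658 of them higher; lowest adjusted p 0.116, for a gene without a name). The 12 lists had an adjusted p between 0.554 and 0.818 with an estimated correlation, so none kept its call, and fry called 0 of 38 (lowest adjusted p 0.476). As a further limit, 54 of 100 splits of the arrays gave as many lists. With slide as a fixed block the medians were -0.66 for fibroblast, -0.26 for matrix, -0.42 for macrophage, 0.36 for glucocorticoid-responsive, 0.15 for fatty acid oxidation and 0.48 for T and B cell genes. They were -0.17 for interferon-responsive, -0.13 for ribosomal, -0.17 for heat shock, -0.40 for smooth muscle, -0.26 for endothelial and -0.24 for liver genes. Among the 4 same-slide pairs, the fibroblast median ran from -1.34 to 0.65, the matrix median from -0.85 to 0.18 and the macrophage median from -1.11 to 0.29, with 3, 3 and 2 pairs below 0. The glucocorticoid-responsive median ran from -0.05 to 0.77 with 3 pairs above 0. Carbon black day 1 replicate 6, which was low in atrial transcripts, also scored lowest of its group for endothelial (-1.82) and smooth muscle markers (-1.66).

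At day 3 after instillation no single gene passed, and the ion channel and calcium handling, cell cycle and airway lists were called with the preset correlation. The sarcoplasmic reticulum calcium-binding protein Hrc differed by 1.14 ± 0.43 (SE; 5 against 6 arrays) and the potassium channel Kcnd2 by 1.13 ± 0.48. In this list 22 of the 24 members were above 0, with a median of 0.26 (camera, adjusted p = 0.0237, and adjusted p = 0.92 with an estimated correlation), and none passed over all genes or adjusted over the list alone. Within slides this median was -0.04, with 1 of 3 pairs above 0. Cell cycle genes had a median of -0.24, or 0.20 with median centring, where the median of all genes was 0.285 (19 of 24 below 0, adjusted p = 0.0229, and adjusted p = 0.92 with an estimated correlation), with Plk1 at -0.41 ± 0.15 and Aurka at -0.36 ± 0.16. Lung and airway markers had a median of -0.49 (6 of 7 below 0, adjusted p = 0.0229, and adjusted p = 0.92 with an estimated correlation). The club cell secretory proteins Scgb1a1 and Scgb3a1 stood at -1.84 ± 0.58 and -1.51 ± 0.45 and the club cell cytochrome Cyp2f2 at -1.70 ± 0.67. These 3 passed adjusted over the list alone, none over all genes. The airway score was 1.00 ± 1.25 (SD, n = 6) in control day 3, where replicate 1 reached 3.01, and 0.22 ± 0.36 (SD, n = 5) in the exposed group.

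Among single genes at day 3, those of smallest unadjusted p were Ints13, an Integrator complex subunit (0.66 ± 0.16), Zfp119a (0.51 ± 0.11), the deubiquitinase Usp8 (0.46 ± 0.11), the SUMO protease Senp7 (0.45 ± 0.11), Ogfod2 (-0.43 ± 0.09) and the hexosaminidase Hexdc (-0.41 ± 0.10). Each had a limma adjusted p = 0.346 and 5 of 5 exposed arrays on that side of the control mean, again on the arrays that selected the genes. The 3 other probes of Senp7 gave -0.13, -0.02 and 0.24. Limma called 0 genes, while 2196 had an unadjusted p under 0.05, 1377 of them higher. The 3 lists each had an adjusted p = 0.92 with an estimated correlation, and 96 of 100 splits of the arrays gave as many lists. With slide as a fixed block their medians were 0.28, -0.20 and -0.71. In the 3 same-slide pairs the ion channel median ran from -0.32 to 0.52, the cell cycle median from -0.27 to -0.02 and the airway median from -2.72 to -0.05.

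At day 28 no single gene passed, and 11 lists were called with the preset correlation, with the smallest p for cell cycle genes and the largest median for adipose markers. Fatty acid oxidation genes had a median of 0.32 with 29 of 31 members above 0 (camera, adjusted p = 6.45e-07, and adjusted p = 0.724 with an estimated correlation). They included the lipid droplet protein Plin5 (0.65 ± 0.30; SE, 5 against 6 arrays) and the mitochondrial thiolase Acaa2 (0.41 ± 0.18). Oxidative phosphorylation genes had a median of 0.23 with 33 of 36 above 0 (adjusted p = 4.25e-06, and adjusted p = 0.819 with an estimated correlation), with Cox7a1 at 0.45 ± 0.21 and Cyc1 at 0.43 ± 0.24. Contractile genes had a median of 0.23, or -0.11 from the sample channel alone, with 18 of 20 above 0 (adjusted p = 0.000874, and adjusted p = 0.819 with an estimated correlation), with Tnni3 at 0.73 ± 0.38 and Myl3 at 0.68 ± 0.35. Clock genes had a median of 0.15 with 13 of 18 above 0 (adjusted p = 0.000874, and adjusted p = 0.482 with an estimated correlation). The output transcription factors Dbp (1.24 ± 0.38) and Hlf (0.81 ± 0.30) and the nuclear receptors Nr1d2 (0.77 ± 0.25) and Nr1d1 (0.67 ± 0.20) passed adjusted over the list alone, and none passed over all genes. The 2 other probes of Nr1d1 gave 0.13 and -0.19. Cell cycle genes had a median of -0.26 with 23 of 24 below 0 (adjusted p = 2.36e-07, and adjusted p = 0.724 with an estimated correlation), with the mitotic activator Cdc20 at -0.38 ± 0.17 and Aurka at -0.34 ± 0.16.

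Also called at day 28 were glucocorticoid-responsive genes (median 0.31, 16 of 21 above 0, adjusted p = 0.0113, and adjusted p = 0.819 with an estimated correlation; Mt1 0.44 ± 0.17, Tsc22d3 0.37 ± 0.18). Interferon-responsive genes followed (-0.13, 21 of 27 below 0, adjusted p = 0.000376, and adjusted p = 0.724 with an estimated correlation; Irf7 -0.47 ± 0.21, Stat2 -0.35 ± 0.15). Immediate early genes had a median of -0.18 (18 of 24 below 0, adjusted p = 0.0123, and adjusted p = 0.824 with an estimated correlation; Btg2 -0.56 ± 0.30). Endoplasmic reticulum stress genes had one of -0.13, or 0.04 with median centring (16 of 20 below 0, adjusted p = 0.0117, and adjusted p = 0.819 with an estimated correlation; Atf4 -0.49 ± 0.17), matrix genes one of -0.12, or 0.05 with median centring (27 of 36 below 0, adjusted p = 0.0044, and adjusted p = 0.819 with an estimated correlation; Sparc -0.35 ± 0.14). Adipose markers had a median of 0.39 (17 of 19 above 0, adjusted p = 0.00868, and adjusted p = 0.824 with an estimated correlation; Cidea 0.60 ± 0.24), or -0.06 with the atrial score as a covariate. The atrial score was 0.04 ± 0.26 (SD, n = 5) in exposed hearts and -0.43 ± 1.15 (SD, n = 6) in controls, where replicate 2 stood at -2.72. Apart from the clock list, no member of the 11 lists called at day 28 passed adjusted over its list alone.

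Limma called 0 genes at day 28 (590 at unadjusted p under 0.05, 316 of them higher). The genes of smallest unadjusted p were Nr1d1 (0.67 ± 0.20), Zfp809 (0.54 ± 0.15), the volume-regulated anion channel subunit Lrrc8a (0.46 ± 0.12), the ubiquitin ligase Siah1a (0.39 ± 0.10), the vesicle coat protein Sec13 (-0.33 ± 0.10) and the chaperonin subunit Cct2 (-0.32 ± 0.10). Each had an adjusted p = 1 in limma and 5 of 5 exposed arrays on that side, on the arrays that selected the genes. The 11 lists had an adjusted p from 0.482 (clock genes) to 0.824 with an estimated correlation, and 37 of 100 splits of the arrays gave as many lists. With slide as a fixed block the medians were 0.30 for fatty acid oxidation, 0.17 for oxidative phosphorylation, 0.17 for contractile, 0.20 for clock and -0.23 for cell cycle genes. They were 0.30 for glucocorticoid-responsive, -0.07 for interferon-responsive, -0.27 for immediate early, -0.08 for endoplasmic reticulum stress, -0.09 for matrix and 0.65 for adipose genes. In the 3 same-slide pairs the fatty acid oxidation median ran from -0.18 to 0.87 and the oxidative phosphorylation median from -0.16 to 0.57. The contractile median ran from 0.12 to 0.27, the clock median from 0.03 to 0.35 and the cell cycle median from 0.00 to 0.10. The adipose median ran from -2.1 to 1.68, with 2 of 3 pairs below 0.

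**Figure D3:**
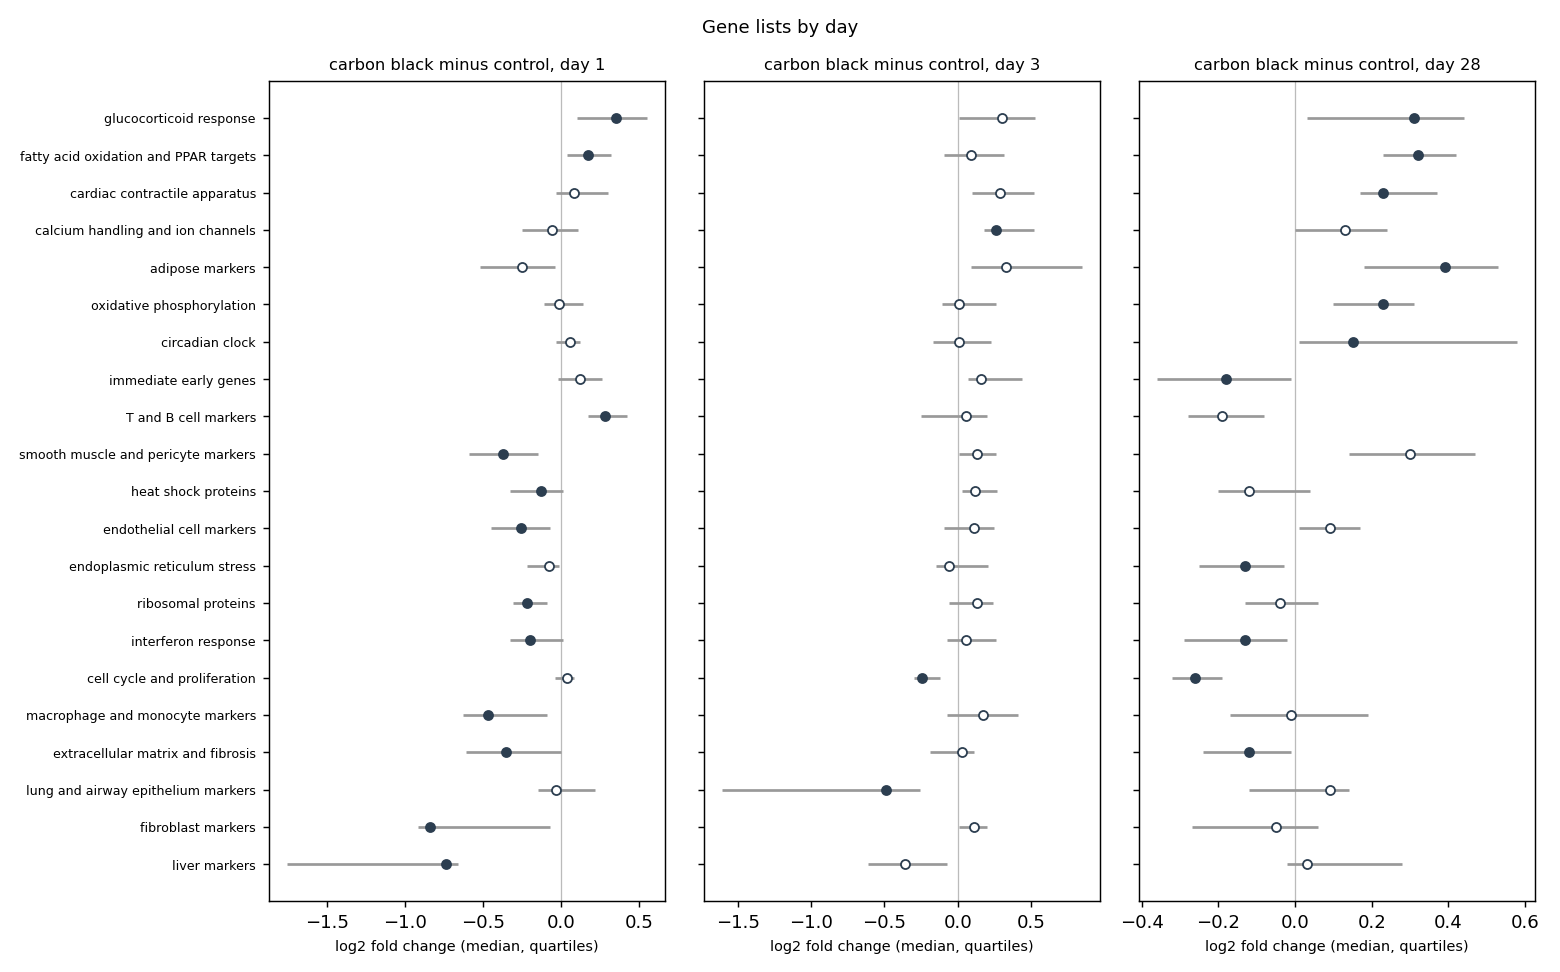
Median log2 fold change of carbon black over control with quartiles over the members of each gene list, by day. Filled points have a camera adjusted p under 0.05 with the preset correlation, open points do not. Fibroblast markers lie lowest among the filled points at day 1 (-0.84, 16 members), and fatty acid oxidation genes at 0.32 (31 members) at day 28. With median centring the day 1 median of all genes moves to 0.208. The day 1 medians of matrix, interferon and endothelial genes then lie above 0 but below 0.208. Those of ribosomal (0.39) and heat shock genes (0.36) lie above it.

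Lists of the inflammatory and acute phase responses that a lung exposure to particles is studied for did not pass in the heart over the days together. Their medians were -0.06 for acute phase genes (camera adjusted p = 0.234), -0.04 for cytokines and chemokines (0.684) and 0.00 for endothelial activation and coagulation genes (0.999). They were 0.00 for Nrf2 targets (0.999), 0.00 for the 7 neutrophil markers tested (0.812) and -0.10 for interferon-responsive genes (0.131). On the single days the acute phase medians were -0.12, -0.07 and 0.00 and the cytokine medians 0.00, -0.02 and -0.10 at day 1, day 3 and day 28, none past the threshold. The acute phase list shares Fgb (-2.22 ± 0.8 at day 1) with the liver list, whose scores varied between arrays. The acute phase medians thus may not read heart tissue alone. Among the other lists, cardiac stress and fetal genes had a median of 0.01 (0.687), metallothionein and hypoxia genes 0.04 (0.999), p53 targets 0.03 (0.999), glycolysis genes 0.02 (0.769) and cholesterol and fatty acid synthesis genes -0.11 (0.15). Cell type markers had medians of 0.17 (0.15) for atrial, 0.22 (0.15) for epicardium, 0.12 (0.15) for platelet, 0.10 (0.292) for skeletal muscle, 0.01 (0.945) for nerve, -0.03 (0.812) for thymus and -0.08 (0.684) for erythroid lists. Fibroblast markers had a median of -0.24 (0.131), with the matrix protein Dpt at -0.58 ± 0.18 (1 member passed adjusted over the list alone, none over all genes), Col3a1 at -0.45 ± 0.23 and Col1a1 at -0.34 ± 0.19. Their same-slide median was below 0 in 6 of 10 pairs, with 3 of 3 at day 28 and 0 of 3 at day 3. The medians were -0.14 (0.163) for macrophage, -0.05 (0.687) for endothelial, -0.01 (0.999) for smooth muscle, 0.00 (0.999) for T and B cell, -0.45 (0.131) for liver, 0.10 (0.364) for adipose and -0.21 (0.201) for airway markers.

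Whether an effect differed between days was tested as the interaction of exposure and day. No gene passed the moderated F test of limma (199 at unadjusted p under 0.05, lowest adjusted p 1), so no gene or list above is shown to be specific to a day. In camera with the preset correlation 13 lists differed between the day 3 and day 1 effects, 15 between day 28 and day 1, and 8 between day 28 and day 3. None did with an estimated correlation (lowest adjusted p = 0.416, 0.574 and 0.522 with an estimated correlation). Across genes, which are not independent replicates, the effects correlated at r = 0.43 between day 1 and day 3, 0.24 between day 1 and day 28 and 0.49 between day 3 and day 28. Such a correlation was reached by 5, 19 and 6 of 100 splits of the arrays within days, the real one included.

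The control groups of the 3 days were compared with each other to show what differed without exposure. From day 1 to day 28 immediate early genes stood higher, with 24 of 24 members above 0 and a median of 0.36 (camera, adjusted p = 9.67e-17; adjusted p = 0.116 with an estimated correlation). They included the orphan receptor Nr4a1 (1.59 ± 0.50; SE, 6 against 6 arrays), Atf3 (1.27 ± 0.52), the MAP kinase phosphatase Dusp1 (0.72 ± 0.28) and Btg2 (0.68 ± 0.28). Interferon-responsive genes had a median of 0.20 (25 of 27 above 0, adjusted p = 4.93e-09; 0.116 with an estimated correlation), with Psmb9 at 0.61 ± 0.28. Clock genes had a median of -0.10 (13 of 18 below 0, adjusted p = 0.00177; 0.145 with an estimated correlation), with Dbp at -0.80 ± 0.36, Tef at -0.78 ± 0.28 and Nr1d2 at -0.56 ± 0.24. Liver markers had a median of -0.81 from day 1 to day 28 (adjusted p = 1.69e-09; adjusted p = 0.116 with an estimated correlation) and -1.60 from day 3 to day 28 (9 of 9 below 0, adjusted p = 5.87e-10; adjusted p = 0.184 with an estimated correlation).

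From day 1 to day 3 the airway genes Scgb1a1 (1.84 ± 0.56), Cyp2f2 (1.72 ± 0.64) and Scgb3a1 (1.6 ± 0.43) stood higher in controls and passed adjusted over the list alone. Of the airway markers 7 of 7 were above 0 (median 0.68, camera adjusted p = 1.22e-06; adjusted p = 0.129 with an estimated correlation). From day 3 to day 28 these 3 genes stood lower, at -1.94 ± 0.56, -2.06 ± 0.64 and -1.68 ± 0.43. Cholesterol and fatty acid synthesis genes had a median of 0.28 from day 1 to day 3 (27 of 28 above 0, adjusted p = 6.85e-08; 0.58 with an estimated correlation), with farnesyl diphosphate synthase (Fdps) at 0.29 ± 0.14. The median was -0.34 from day 3 to day 28 (24 of 28 below 0, adjusted p = 7.37e-06; 0.748 with an estimated correlation), with the squalene synthase Fdft1 at -0.72 ± 0.25. The day 1 to day 3 median was -0.01 without the 3 control day 3 arrays of high liver score. In the limma fit 0 genes passed between the controls of any pair of days (405, 233 and 882 at unadjusted p under 0.05 for day 1 to 3, day 1 to 28 and day 3 to 28). In camera 10, 19 and 8 lists were called with the preset correlation, 0 with an estimated one. With slide as a fixed block the medians were 0.26 for immediate early, -0.06 for clock and -0.64 for liver genes from day 1 to day 28, and 0.01 for airway and 0.45 for cholesterol genes from day 1 to day 3. From day 3 to day 28 they were -1.95 for liver, -0.09 for airway and -0.35 for cholesterol genes.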

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

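A Dixon gap test on the 6 groups looked for a single array apart from its group, in 96 groups of marker scores and 144 groups of named-gene values. Of these 240 groups, 28 had such an array (17 and 11), against 12 expected by chance at 1 in 20. The tests of array position, of section content by 3 scores and of exposure as a source of liver transcripts were chosen after the result was seen. So was the grouping of liver markers by how they move. The tests of splits, liver RNA and clock phase were written before. For signal strength and ratio scale the predictions were written before, but the covariate fits were added after seeing the data.

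Atrial scores stood apart and low in control day 1 replicate 2 (-2.86), carbon black day 1 replicate 6 (-3.13), control day 3 replicate 4 (-2.86), carbon black day 3 replicate 2 (-1.94) and control day 28 replicate 2 (-2.72). Carbon black day 1 replicate 6 also stood apart for endothelial (-1.82), smooth muscle (-1.66), erythroid (-1.2) and skeletal muscle markers (-0.43), and for Nt5e (0.11) and Atf4 (-1.47). Control day 28 replicate 6 stood apart and high for T and B cell (2.56), macrophage (0.79), thymus (0.42) and airway markers (0.6). Carbon black day 3 replicate 4 was high for T and B cell markers (1.21) and carbon black day 28 replicate 1 for airway markers (0.41). Control day 28 replicate 5 was low for endothelial markers (-0.54). Control day 28 replicate 2 was low for fibroblast markers (-0.86), Actg1 (-1.84), Ubb (-0.24) and Sfn (-1.42). Among single genes, control day 1 replicate 2 stood apart for Col4a1 (2.32), control day 3 replicate 6 for Nfkbia (-0.07), control day 3 replicate 1 for Niban2 (-0.53), carbon black day 3 replicate 2 for Gstm1 (1.13), control day 28 replicate 4 for Gstm1 (0.43) and carbon black day 28 replicate 5 for Mfap3 (-0.99).

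The change of Ephx2, Sparc and the other genes called over all days together was weighed against 4 causes other than exposure. Of the 400 genes of smallest p on the 20 arrays in same-slide, same-day pairs, 88.5% went the same way on the 14 other arrays, but 17 of 100 shuffles there, the real labels included, reached that share (highest 96.5%), and on those arrays the arms lie on separate slides, which the shuffles ignore, so exposure and array position cannot be told apart. The median change in the direction of each gene was 0.352 with the atrial, adipose and liver scores as covariates, against 0.361 without. It was 0.353 with the ratio slope. These medians come from the arrays that selected the genes. The median also stayed at 0.364 with slide as a fixed block, where 0 genes passed, so a median alone cannot speak against a cause. With the 3 scores 589 genes passed, 291 of them among the 386, and with the ratio slope 416 passed, 342 of them among the 386. Adjusting for these scores or for the slope thus did not remove the calls. Liver content stays open, as 1 gene passed without the 3 control day 3 arrays of high liver score (median 0.327), on fewer arrays. The share of cardiomyocytes or fibroblasts was not tested. The median was 0.334 with the share of spots well above background, where 0 genes passed (2894 at unadjusted p under 0.05). Exposure and signal strength thus cannot be told apart either. Of 100 splits of the arrays within days, 2 gave at least 386 genes, the real split itself and 1 other (717).

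Of the 9 liver markers, Alb, Fgb, Apoa1, Apoa2, Apoc3 and Cyp2c29 moved together over arrays (pairwise r from 0.73 to 0.96). Mup1 followed them less (0.53 to 0.68), and Trf (0.24 to 0.39) and Ahsg (0.17 to 0.25) least. The median pairwise correlation of all 9, as deviations from group means, was 0.63, against at most 0.24 in 1000 random lists, consistent with RNA from liver tissue in some sections, although Ahsg and Trf did not follow. The liver score differed by -0.41 between exposed and control arrays over the days together (permutation p = 0.24). That mean takes in day 28, where Alb deviated only by -0.9 to -0.05 from its median, and also Ahsg and Trf. At day 1 Alb ran from 1.21 to 3.9 in controls and from -0.6 to 2.85 in exposed hearts (limma adjusted p = 0.458). At day 3 it ran from -0.69 to 4.57 and from -0.46 to 3.92. The permutation did not test this difference by day. A part for exposure cannot be told apart from uneven sections.

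Clock output genes Dbp (1.24), Hlf (0.81), Nr1d2 (0.77) and Nr1d1 (0.67; other probes 0.13 and -0.19) stood above 0 at day 28, but none passed over all genes (limma adjusted p = 1) and the list had an adjusted p = 0.482 with an estimated correlation. The 4 tested genes of opposite phase had a mean change of -0.24 ± 0.17 (SE over genes), 3 of them below 0: Arntl -0.63, Nfil3 -0.42, Npas2 -0.01 and Clock 0.10. The day 28 controls, which enter both contrasts, differed from the day 1 controls by -0.80 ± 0.36 for Dbp, -0.78 ± 0.28 for Tef and -0.56 ± 0.24 for Nr1d2, so the difference may lie in the controls as well as in exposed hearts. The opposite-phase mean of -0.24 was just past the limit written beforehand for a shift in collection time. With an SE of 0.17 it is not clearly apart from 0, and it rests on Arntl and Nfil3. It thus cannot decide between a different time of day of collection in the 2 groups of day 28, an effect of exposure on the clock, or neither.

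Splits of the arrays within the groups compared, with the real one among the 100, gave these results. A count of 0 genes is reached by each of 100 splits by construction, and so tells nothing, at day 1 (highest other 17), day 3 (43) and day 28 (0), for the difference between days (54) and for controls day 1 to 3 (663), day 1 to 28 (0) and day 3 to 28 (222). Counts at unadjusted p under 0.05 as large as the real ones came from 25, 11 and 60 of 100 splits at day 1, day 3 and day 28, and from 87, 91 and 59 for the controls in the same order. For lists with the preset correlation, 54 of 100 splits reached the real 12 at day 1 (highest other 23), 96 the real 3 at day 3 (21), 37 the real 11 at day 28 (21) and 93 the real 5 over all days together (21), so the number of called lists is no larger than regrouped arrays give.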

How the results depend on the processing

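The count over all days together (386 genes, 262 higher and 124 lower, 67.9% higher) depended most on the choices made. It was 1487 without background correction, 0 with Agilent processed signals (2163 at unadjusted p under 0.05), 1336 with median centring (1336 higher, 0 lower), 1491 with the authors' value table (819 higher, 672 lower, 54.9% higher), 153 without the filter on dim probes, 140 with the mean of a gene's probes, 1491 with array weights, 1248 at adjusted p under 0.1 and 36 with a fold of 1.5. It was 0 with slide as a fixed block (2850 at unadjusted p under 0.05), 0 with scan day (3209) and 0 within slides (3642). It stayed at 386 with Aquantile, which leaves ratios unchanged, and was 444 with the sample channel alone (382 higher, 62 lower, 86% higher), 403 with probes well above background on all arrays, 477 with every probe, 437 with slide as a random block and 451 with trend and robust. Alternatives chosen after seeing the data gave 0 with position (1501), 723 with the atrial score, 589 with 3 scores, 0 with the share of spots well above background (2894), 416 with the ratio slope, 1022 without the 5 arrays of low atrial score, 1 without the 3 control day 3 arrays of high liver score (2875), 361 on the 20 arrays in same-slide, same-day pairs and 0 on the 14 other arrays (1308). At day 1 the count was 1 with scan day, 6 with the atrial score and 4 with 3 scores; for controls day 1 to 28 it was 1 with only the groups compared. The cause was not tested. Signal over background limits which genes can be read at all.

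Of 24 called genes in all settings 750 of 1464 values kept the call, 710 lost it and 4 reversed; of 41 list results 2177 of 2521 values kept it, 311 lost it and 33 reversed. Median centring moved the median of all genes by 0.188 over all days, 0.208 at day 1, 0.285 at day 3 and 0.079 at day 28. With it reversed values were Arf1 0.04, Sfn 0.01, Sparc 0.02 and Ubb 0.11, cell cycle 0.19 over all days and 0.20 at day 3, matrix 0.17 over all days, 0.10 at day 1 and 0.05 at day 28, endoplasmic reticulum stress 0.04 at day 28, and at day 1 endothelial 0.03, heat shock 0.36, interferon 0.11 and ribosomal 0.39. Endothelial markers at day 1 also reversed without background correction (0.22), with Agilent processed signals (0.26), the value table (0.20), within slides (0.02), on the 20 paired arrays (0.02), without carbon black day 1 replicate 6 (0.06, against -0.35 without its replicate 4) and without the 5 arrays of low atrial score (0.05). Adipose markers at day 28 reversed with the atrial score (-0.06) and 3 scores (-0.09); with 3 scores so did liver markers in controls day 1 to 28 (0.34) and at day 1 (0.19), but the 3 scores are means of the adipose and liver markers themselves, so these 3 values are fixed by the model and are no test of the result. Ion channel genes at day 3 (-0.04) and cell cycle genes at day 28 (0.05) reversed within slides, and again on the 20 paired arrays (-0.04 and 0.05), where cholesterol genes of controls day 1 to 3 gave -0.03; these gave -0.01 without the 3 arrays of high liver score. On the 14 other arrays matrix genes (0.20) and immediate early genes (0.14) reversed at day 28, as did immediate early genes of controls day 1 to 3 (-0.01) and airway markers of controls day 3 to 28 (0.14). Contractile genes at day 28 gave -0.11 with the sample channel alone, and immediate early genes of controls day 1 to 3 gave -0.02 with slide fixed.

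Leaving out each array gave 0 to 3 genes at day 1 (3 without carbon black day 1 replicate 3, 1 without its replicate 4, 1 without control day 28 replicate 6), 0 to 1 at day 3 (1 without control day 3 replicate 5), 0 to 0 at day 28, between days and in controls, and 0 to 947 over all days. Over all days the count without a control array was 706, 54, 203, 68 and 692 for day 1 replicates 2 to 6, 10, 735, 947, 14 and 50 for day 3 replicates 1, 2, 3, 4 and 6, and 132, 653, 143, 0 and 20 for day 28 replicates 1 to 5. Without a carbon black array it was 67, 147, 17, 30 and 819 for day 1 replicates 1, 2, 4, 5 and 6, 137, 133, 0 and 0 for day 3 replicates 1, 2, 3 and 5, and 141, 0 and 52 for day 28 replicates 2, 3 and 5.

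All 41 list calls were lost with an estimated correlation and with fry. No paired analysis was possible because the labels match no animals and give only array numbers over the whole study, so the same-slide pairs match arrays and not animals. Normexp on median signals is the main setting, as only median signals were used; slide as a random block and trend with robust were not run for lists.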

Other observations

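Genes that narrowly missed the threshold over all days together lie close to those that passed. Fkbp5 (1.07 ± 0.30), the calcium-binding protein Hrc (0.89 ± 0.25), the heart form of a cytochrome oxidase subunit, Cox6a2 (0.45 ± 0.12), and the antiviral tether Bst2 (-0.40 ± 0.11) had limma adjusted p of 0.0521, 0.0502, 0.0502 and 0.0521.

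Hypothesis 1 is that liver tissue was carried into some heart samples. With a median marker correlation of 0.63 it could be tested by measuring albumin and apolipoprotein transcripts in the same RNA and in a newly trimmed section of the same hearts.

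Hypothesis 2 is that exposed and control hearts of day 28 were collected at different times of day. The mean change of -0.24 ± 0.17 (SE over genes) for opposite-phase clock genes leaves this open. Collection times of each mouse, or new groups collected in alternating order, would test it.

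Hypothesis 3 is that the all-days change in Ephx2, Ldhb and Spp1 follows array position. On the 14 arrays outside the same-slide pairs, none of them at position 4, 88.5% of the 400 chosen genes went the same way. As 17 of 100 shuffles reached that share, position stays open. Hybridising the same RNA again with both arms balanced over positions, or quantitative PCR of Ephx2, Ldhb and Spp1, would test the hypothesis.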
